A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

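The series holds 7 samples, of which 4 measured nascent RNA and 3 measured Hsf1 binding by chromatin immunoprecipitation. The binding samples were not analysed here. The labels give the nascent RNA strain as an Hsf1 anchor-away strain with FLAG-tagged Rpb3, and the treatments as 30 °C or 39 °C, with or without 1 µM rapamycin. How long the cells were at 39 °C before nascent RNA was taken, and how long they had rapamycin, is not given in the sources used here. No strain without the anchor-away tag was analysed here, so that removal of Hsf1 and any other action of rapamycin go together in every rapamycin comparison.

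The deposited table gives, per the file headers, an average normalized read count (a signal value) for each of 5732 genes in each of the 4 conditions. Its 4 columns were matched to the conditions by their header abbreviations, of heat shock, no heat shock and rapamycin. Counting with HTSeq on genome build sacCer3 is named per the submitters' processing notes. The versions, the aligner of the nascent RNA reads, the annotation, the strand setting, the treatment of reads that map to several places and the scaling method are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies such as SSA1 and SSA2, SSA3 and SSA4, HSP82 and HSC82, SSB1 and SSB2, TDH2 and TDH3 and the paired ribosomal protein genes, were therefore treated as uncertain in their split. Nascent RNA purified through polymerase can carry mature RNA along, and the table does not separate them.

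What the columns hold was checked on the values. Every value was a multiple of 0.005, as the mean of 2 numbers with 2 decimals would be. Low values, those under 6, fell on sums of whole multiples of 2 steps per column within 0.0055, for 99.2% to 100% of such values against 5.5% to 25.7% by chance. The chance share is that of evenly spaced values near the steps already fitted, without refitting, so it is too low as a baseline. The share of fitted sums met by a value ran from 71.5%, at 30 °C without rapamycin, to 100%. Only 2 steps per column were fitted, so another number of libraries was not compared. The steps were shared by genes of any length. From this each column was read as the mean of 2 libraries scaled by 1 factor each, without division by gene length. The steps give estimated depths of 795000 and 371000 reads for 30 °C without rapamycin, 498000 and 373000 for 30 °C with rapamycin, 576000 and 341000 for 39 °C without rapamycin and 300000 and 205000 for 39 °C with rapamycin. The libraries cannot be separated, so there is no SD, n or test. Counting error alone would be 11.3%, 12.3%, 13.4% and 17.1% of a value at the median gene of each condition in that order, and 2.7% to 4.0% at a value of 500. No gene had a value of 0. The steps were fitted with at least 1 read of each averaged library behind every value, which is assumed and not shown. Intervals and standard errors cover counting error only, and reads without molecular identifiers are not independent molecules.

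For each gene the log2 ratio of 2 conditions was computed after adding 2.851, which is 0.1 of the median value, to each. Genes were kept if their mean over the 4 columns was at or above the 20th percentile, 14.442, which kept 4585 genes and left 1147 out. A gene was counted as higher or lower at a log2 ratio of at least 1 or at most -1. The 4 comparisons were heat shock without rapamycin, rapamycin at 30 °C, rapamycin during heat shock and heat shock with rapamycin, and the difference of the rapamycin ratios was taken between temperatures. The design had been written for 1 library per condition, and the averaged columns were analysed in the same way. Column values were used as deposited. Median-ratio factors computed over them were 1.003, 1.006, 1.011 and 1.007.

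Gene lists and planned settings were fixed from general knowledge before the data were examined. Membership was not checked against binding or promoter motifs, so a list name does not show which factor acts on each member. The shared list holds KAR2, ERO1, CPR1, SSC1, PDR3 and RPN4, whose control by Msn2/4 was not checked. HSP104, HSP42 and HSP78 were placed in the Hsf1 list, which does not exclude control by Msn2/4. Lists with measured members were the Hsf1 chaperone regulon (21), Hsf1 and Msn2/4 shared genes (14), the Msn2/4 general stress regulon (29), ribosomal protein genes (135), ribosome biogenesis genes (61), proteasome genes (33), endoplasmic reticulum folding genes (20), ribosome-associated and TRiC chaperones (20) and Yap1 oxidative stress genes (20). The others were Pdr1/Pdr3 drug resistance genes (11), nitrogen catabolite genes (23), Gcn4 amino acid genes (36), respiration genes (36), glycolysis genes (16), reference genes (8), histone genes (9), the phosphate regulon (9) and pheromone and mating genes (14). The Yap1 and Pdr1/Pdr3 lists share 1 gene. Listed names that matched no row were left out, and why they were absent was not checked. They were 4 each of the ribosome biogenesis, phosphate and pheromone lists and 2 of the nitrogen catabolite list. The Msn2/4, ribosome-associated and TRiC, Yap1, Gcn4 and reference lists lacked 1 each. No gene had a value of 0, so genes without reads in a condition may be missing. Mitochondrially encoded, small nucleolar RNA, transfer RNA and Ty element genes were not analysed here as lists. Ty genes with a row were not removed from the table. List medians and the counts of list members past 2-fold cover all measured members, those under the filter included. Each was placed among 10000 random lists of the same size drawn from the same deciles of mean value.

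The named genes followed a rule fixed at the same time. In each comparison they are every measured member of the Hsf1 regulon, with full values for the 4 with the largest absolute ratio, the 10 highest and 10 lowest kept genes, and the 2 members of each other list with the largest absolute ratio. HSF1, MSN2, MSN4, RPB3, TOR1, RPL13A and ACT1 were named in every condition as checks. FPR1 of the same rule matched no row by name. The 5 largest and 5 smallest genes were named for the difference. Genes under the filter were named only as list members. Other genes named were chosen after their values were seen, which the text says. Gene symbols and coordinates came from the RefSeq gene table of assembly R64, the same assembly as sacCer3, in which 5351 of the 5732 identifiers were found by locus tag and 381 were not.

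Alternatives were a pseudocount of 0.01 or 0.5 of the median, no filter or a filter at the 40th percentile, rescaling by median-ratio factors, to equal totals or by TMM, and thresholds of 1.5-fold and 3-fold. Removal of the trend of the log2 ratio on gene length, by local regression with a span of 0.3, was added after the data were seen. The counting was tested on simulated data for the 4585 kept genes with 200 changed genes. Of the genes changed 3-fold, 96%, 97%, 97% and 96% were recovered in heat shock without rapamycin, rapamycin at 30 °C, rapamycin during heat shock and heat shock with rapamycin, and 100% of those changed 6-fold in each. Counting error carried 0, 0, 12 and 5 of 4385 unchanged genes past 2-fold. In the list step, tested for rapamycin at 30 °C on lists of 20 genes, a list changed 2-fold reached percentile 100, and 2 of 20 unchanged lists fell outside the middle 95%. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.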

Results

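The nascent RNA part of the study measured transcription in a Saccharomyces cerevisiae strain in which Hsf1, the transcription factor that drives chaperone genes, carries an anchor-away tag. In such strains rapamycin tethers the tagged protein to an anchor outside the nucleus, so that the factor is removed from its targets. The strain also carries a FLAG tag on Rpb3, a subunit of RNA polymerase II, the enzyme to which nascent RNA is attached. The 4 conditions were 30 °C and 39 °C, each without and with 1 µM rapamycin, with 1 sample per condition in the labels. The 3 Hsf1 chromatin immunoprecipitation samples of the series were not analysed here. Values are the authors' mean normalized read count per gene for 5732 genes, deposited as 1 column per condition. The columns summed to 377862.5 at 30 °C without rapamycin, 369160.1 at 30 °C with rapamycin, 433510.0 at 39 °C without rapamycin and 397419.1 at 39 °C with rapamycin.

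No replicate values were used, so no difference below has a replicate check or a test. Genes are described as higher or lower by a fixed rule of size, at least 2-fold on the log2(value + 2.851) scale. Counts over all genes cover the 4585 genes that passed a filter on low values, while list counts and medians cover all measured members, those under the filter included. This scale understates the change of genes with low values. The standard errors given with some ratios cover counting error only. A list median is set beside the middle 95% of the medians of 10000 random gene lists matched on mean expression, which describes these libraries and tests nothing. Coordinates are those of the S288C assembly R64 and span the whole annotated gene.

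The genes of the tagged or tethering system and the control genes were read in every condition. HSF1 (YGL073W, chromosome VII, 368753 to 371254) had 78.7 and 60.3 normalized reads at 30 °C without and with rapamycin, and 113 and 99.98 at 39 °C. Its log2 ratio with rapamycin was -0.37 at 30 °C and -0.18 at 39 °C. The anchor-away method moves the protein, so the HSF1 read count does not check that Hsf1 left the nucleus. RPB3 had 42.0, 46.0, 32.9 and 40.8 normalized reads in the order 30 °C without and with rapamycin, then 39 °C without and with rapamycin. In the same order TOR1, which encodes the rapamycin-sensitive kinase, had 69.5, 73.7, 129 and 70.8, and RPL13A, a ribosomal protein gene, had 95.5, 99.98, 56.2 and 96.9. MSN2 and MSN4, which encode the general stress transcription factors, had 42.3, 45.2, 81.9 and 65.3, and 50.7, 57.5, 50.9 and 62.1. The actin gene ACT1 had 650, 607, 962 and 762. No row matched the name of FPR1, the rapamycin receptor gene, and why was not checked.

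The first comparison asks how transcription responds to heat shock when Hsf1 can reach its targets. At 39 °C without rapamycin, 740 genes were at least 2-fold higher and 820 at least 2-fold lower than at 30 °C. The median log2 ratio of all kept genes was 0.0113, and it lay between -0.0006 and 0.0218 in the comparisons that follow. Higher and lower are therefore in effect relative to the median gene, here and below. The scaling method is not given in the sources used here, so a change in total transcription cannot be read from these counts. Chaperone genes and general stress genes were at the top, and genes for making ribosomes were at the bottom. Every one of the 21 measured genes of the Hsf1 chaperone regulon was at least 2-fold higher, with a median log2 ratio of 3.53, an 11.5-fold difference. All 29 measured genes of the Msn2/4 general stress regulon were higher as well, with a median of 3.88. All 61 measured ribosome biogenesis genes were at least 2-fold lower, with a median of -3.41.

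In the Hsf1 regulon, HSP42 (YDR171W, IV, 806621 to 807748), a small heat shock protein gene, went from 22.6 to 2716 normalized reads, a log2 ratio of 6.74 with a counting standard error of 0.17. BTN2 (YGR142W, VII, 772454 to 773686), whose product gathers misfolded proteins into deposits, went from 15.7 to 1637, a ratio of 6.46 (counting standard error 0.19). HSP78 (YDR258C, IV, 971808 to 974243), a mitochondrial disaggregase gene, had a ratio of 6.01. HSP104 (YLL026W, XII, 88623 to 91349), the cytosolic disaggregase gene, went from 144 to 5932, a ratio of 5.33 with a counting standard error of 0.07. The remaining members, HSP82, HSC82, SSA1, SSA2, YDJ1, SIS1, APJ1, CUR1, MDJ1, HSP60, HSP10, HCH1, AHA1, CPR6, STI1, FES1 and MBF1, had log2 ratios from 1.78 to 5.29. Random lists matched to this regulon had medians between -0.85 and 0.75. The genes listed under both Hsf1 and Msn2/4, a label not checked gene by gene, had 12 of 14 members at least 2-fold higher. Their median was 3.33. They included HSP26 (YBR072W, II, 382030 to 382674), another small heat shock protein gene, which had the highest ratio of all kept genes on this scale at 7.29. Another was the Hsp70 gene SSA4 (YER103W, V, 364589 to 366517) at 6.85, from 28.5 to 3610 normalized reads.

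The other genes among the 10 highest were TMA10 at 6.67, the membrane stress protein gene HSP12 at 6.44, FMP45 at 5.97, and 2 Msn2/4 genes, the trehalose synthase subunit gene TSL1 at 5.89 and the cytosolic catalase gene CTT1 at 5.70. TMA10 stood on only 2 reads at 30 °C, the lowest value of that column, and its raw ratio was 486, above the 321 of HSP26. An approximate Poisson 95% interval of the TMA10 ratio ran from 135 to 4016. Such intervals pool the reads of the 2 libraries and hold the value of the other condition fixed. Among the 10 lowest were the nucleolin-like gene NSR1 at -4.99, the 60S assembly GTPase genes NOG1 at -4.76 and NOG2 at -4.29, NOP4 at -4.70, MAK16 at -4.53, and the rRNA methyltransferase gene NOP1 at -4.44. PUF6 at -4.38, the H/ACA particle gene NHP2 at -4.29 and the small-subunit processome gene UTP4 at -4.26 completed this set. The lowest of all, YGR160W at -5.99, is a dubious open reading frame that overlaps NSR1, and their reads cannot be told apart here. MAK16 stood on 2 reads at 39 °C, the lowest value of that column. It was lower by a raw ratio of 85.3, with an approximate Poisson interval from 23.6 to 705.

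Among the ribosomal protein genes 109 of 135 were at least 2-fold lower, with a median of -1.47. RPL9B at -2.86 and RPL26B at -2.80 were lowest. Ribosome-associated and TRiC chaperones, which fold new proteins, had 5 of 20 members lower and none higher, with a median of -0.41 inside the random range. The ribosome-bound Hsp70 genes SSB1 at -2.24 and SSB2 at -2.03 led that list. Pheromone and mating genes had 9 of 14 members lower and a median of -1.50, below the random range of -0.54 to 0.57, and of -0.909 with a pseudocount of 0.5 of the median. The alpha-factor gene MF(ALPHA)1 at -3.67 and the pheromone receptor gene STE3 at -3.25 were lowest there. Of the 9 histone genes 5 were lower, with a median of -1.08. The H4 gene HHF1 at -1.28 and the H3 gene HHT1 at -1.26 were among them, and random lists of that size ranged from -1.20 to 1.096.

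Respiration genes had 10 of 36 members at least 2-fold higher and a median of 0.73, above the random range of -0.45 to 0.53. The citrate synthase gene CIT1 at 2.001 and KGD1 at 1.79 led them. Endoplasmic reticulum folding genes had 7 of 20 higher and a median of 0.79, led by MPD1 at 2.02 and INO1 at 1.45. INO1 was placed in this list but encodes an inositol phosphate synthase, not a folding factor. Yap1 oxidative stress genes had 7 of 20 higher and a median of 0.69, led by the peroxiredoxin genes AHP1 at 2.59 and PRX1 at 2.40. Both of these medians were above their random ranges, whose upper bounds were 0.53 and 0.59. The Yap1 median was 0.417 with a pseudocount of 0.5 of the median. Inside their random ranges lay the proteasome genes at 0.50 with 1 of 33 higher, the Pdr1/Pdr3 drug resistance genes at 0.76 with 5 of 11 higher and 1 lower, and the glycolysis genes at 0.55 with 3 of 16 higher. RPT2 at 1.01 and RPN2 at 0.91 led the proteasome list, the transporter genes YOR1 at 2.26 and PDR15 at 2.11 the drug resistance list, and TDH1 at 4.22 and ENO1 at 1.98 the glycolysis list. The nitrogen catabolite genes at 0.34, the Gcn4 amino acid genes at -0.07, the phosphate regulon at -0.06 and the reference genes at 0.12 were also inside. Counts past 2-fold in these lists were 7 higher and 2 lower of 23, 1 higher and 3 lower of 36, 2 lower of 9, and none of 8. Their widest members were DUR3 at 1.87 and DAL1 at 1.60, the latter under the filter, LEU9 at -3.19 and ILV3 at -2.34, the phosphate transporter gene PHO84 at -1.63 and VTC1 at -1.37, and TAF10 at -0.90 and ACT1 at 0.56. With every column rescaled to the same total, the counts became 595 higher and 1013 lower, since that scaling shifts the median of all kept genes to -0.17. The reference gene median then turned to -0.061.

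**Figure D1:**
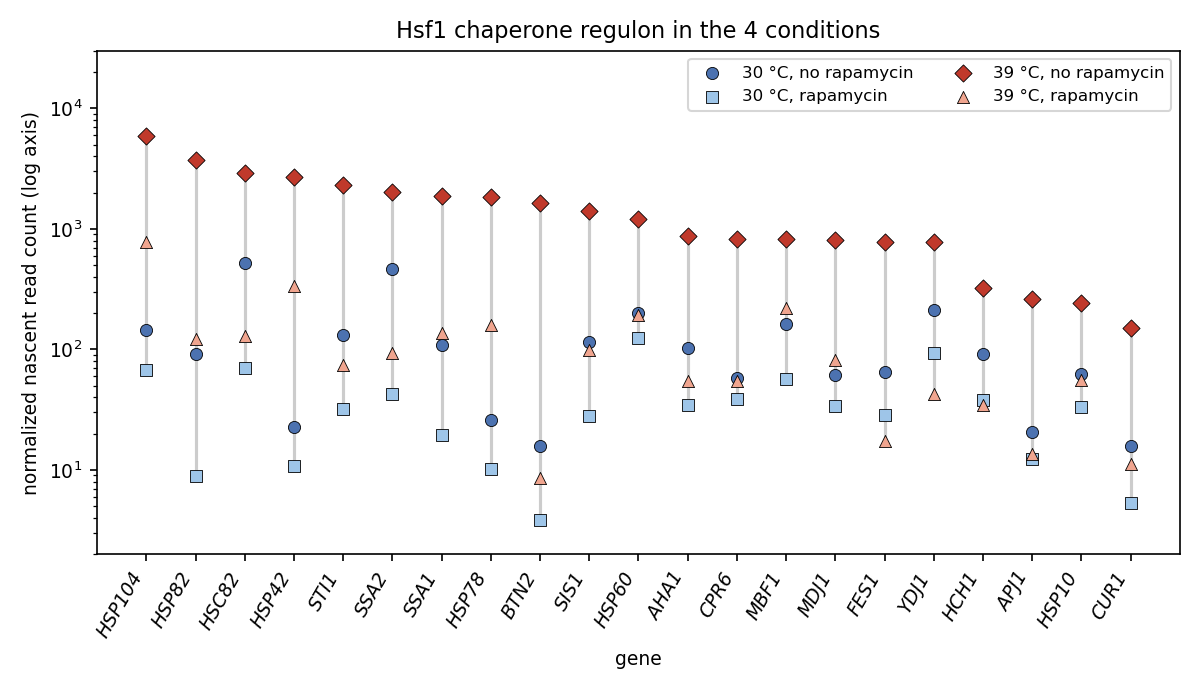
Normalized nascent read count (log axis) of the 21 genes of the Hsf1 chaperone regulon, with 1 point per condition and a grey line from the lowest to the highest. Each point is the authors' mean, without an error bar. All 21 genes are highest at 39 °C without rapamycin, and HSP104 reaches 5932 there against 774 at 39 °C with rapamycin.

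The second comparison asks which genes depend on nuclear Hsf1 without heat shock. With rapamycin at 30 °C, 17 genes were at least 2-fold lower and 2 were at least 2-fold higher, while 97.0% of kept genes lay within 1.5-fold. These counts were 11 lower and 0 higher with a pseudocount of 0.5 of the median. Of the 17 lower genes, 15 belong to the Hsf1 chaperone regulon. That list had a median log2 ratio of -1.20, a 2.30-fold difference, and all 21 members were below 0. The largest differences were in the cytosolic Hsp70 and Hsp90 genes, which encode central chaperones of the cytosol.

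SSA2 (YLL024C, XII, 95566 to 97485), an Hsp70 gene, was at 42.3 normalized reads with rapamycin and 463 without it, a log2 ratio of -3.37 with a counting standard error of 0.14. HSP82 (YPL240C, XVI, 96496 to 98625) and HSC82 (YMR186W, XIII, 632355 to 634472), the 2 Hsp90 genes, had ratios of -3.01 and -2.84 with counting standard errors of 0.26 and 0.12. SSA1 (YAL005C, I, 139503 to 141431) was at 19.5 with rapamycin against 108 without it, a ratio of -2.31. The remaining members ranged from -1.94 to -0.55, including the cochaperone genes STI1 at -1.94, SIS1 at -1.92 and AHA1 at -1.50, BTN2 at -1.48 and the coactivator gene MBF1 at -1.46. SSA1 and SSA2, and likewise HSP82 and HSC82, are near-identical copies, and how shared reads were counted is not given in the sources used here, so the split within each pair is uncertain. The 2 lower genes outside the list were YAL004W at -1.89, a dubious open reading frame that overlaps SSA1, and LST8, a component of the TOR complexes. LST8 (YNL006W, XIV, 620067 to 620978) had a ratio of -1.26 and was singled out after its values were seen. The 10 lowest genes of this comparison are SSA2, HSP82, HSC82, SSA1, STI1, SIS1, YAL004W, AHA1, BTN2 and MBF1.

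The 2 higher genes, PCL8 at 1.04 and LEU5 at 1.03, had low values, 6.89 and 6.11 without rapamycin, with counting standard errors of 0.31 and 0.32. The count of higher genes was 10 with a pseudocount of 0.01 of the median, 5 without the filter and 0 with the filter at the 40th percentile. The rest of the 10 highest, YML002W, SPI1, YDL023C, PUS5, YGR149W, NGL3, CYC2 and RGI1, were between 0.86 and 0.99. YDL023C had no match in the RefSeq gene table and may share reads with GPD1 (YDL022W). The genes shared by Hsf1 and Msn2/4 had a median of -0.21, below the random range of -0.11 to 0.10, and none of the 14 passed 2-fold. The median was -0.133 with a pseudocount of 0.5 of the median. Their largest differences were -0.70 for SSE1, an Hsp110 gene, and -0.59 for CPR1, the cyclophilin A gene. The Msn2/4 list had a median of 0.24, above the random range of -0.08 to 0.07. Of its 29 members 24 were above 0 and none passed 2-fold, with GPD1 at 0.78 and GLK1 at 0.70 leading. Proteasome genes had a median of -0.22 with 30 of 33 below 0, led by PRE6 at -0.64 and RPT1 at -0.52. Pheromone and mating genes had a median of -0.22 with 13 of 14 below 0, and their widest members were FUS1 at -0.54, under the filter, and AGA1 at -0.47.

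Ribosomal protein genes and ribosome biogenesis genes had medians of -0.06 and -0.12, just below their random ranges of -0.04 to 0.03 and -0.06 to 0.06. With equal totals the former was -0.025. RPL15B at 0.44, RPS21A at -0.44, SOF1 at -0.56 and BFR2 at -0.48 were their widest members. Nitrogen catabolite genes, which nitrogen-poor conditions raise, had a median of 0.11 against a random range of -0.11 to 0.10. Their widest members, DAL5 at 0.42 and UGA4 at 0.38, were under the filter. The other 10 lists had medians inside their random ranges, and no member of these or of the lists just named passed 2-fold. The medians were 0.08 for endoplasmic reticulum folding genes, -0.06 for ribosome-associated and TRiC chaperones, -0.02 for Yap1 genes, 0.04 for Pdr1/Pdr3 genes, 0.00 for Gcn4 genes, 0.03 for respiration genes, -0.05 for glycolysis genes, -0.09 for reference genes, 0.01 for histone genes and 0.09 for the phosphate regulon. Rescaled to equal totals, the Yap1 and Gcn4 medians turned to 0.009 and 0.03, and without the length trend to 0.01 and 0.002. With the filter at the 40th percentile the Yap1, Pdr1/Pdr3 and phosphate medians turned to 0.035, -0.018 and -0.029. The widest members were MPD1 at 0.57 and ULI1 at -0.42, BTT1 at 0.68 and GIM5 at 0.57, HSP31 at 0.62 and TRX2 at -0.38, YOR1 at -0.37 and RSB1 at 0.27, and ORT1 at -0.58 and SNO1 at 0.49. For the rest they were CIT1 at 0.56 and QCR9 at 0.46, TDH3 at -0.35 and ENO1 at 0.30, TAF10 at -0.65 and TFC1 at -0.37, HTZ1 and HHF1 at 0.25 and -0.25, and PHO89 at 0.46 and PHO84 at -0.46. ULI1, BTT1, SNO1 and PHO89 were under the filter. PHO89 stood on 2 reads without rapamycin, the lowest value of that column, with a raw ratio of 2.80 and an approximate Poisson interval from 0.8 to 23.1.

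The third comparison asks which part of transcription at 39 °C depends on nuclear Hsf1. With rapamycin during heat shock, 132 genes were at least 2-fold lower and 246 at least 2-fold higher than without it, and 73.7% of kept genes lay within 1.5-fold. All 21 genes of the Hsf1 chaperone regulon were lower, with a median log2 ratio of -3.81, a 13.99-fold difference. Of the 14 genes shared by Hsf1 and Msn2/4, 11 were lower, with a median of -1.90. The Msn2/4 regulon had a median of 0.04, and none of its 29 members passed 2-fold. Ribosomal protein genes and ribosome biogenesis genes were on the higher side, with 72 of 135 and 29 of 61 members at least 2-fold higher. The counts and the biogenesis result depend on the treatment of low values. With a pseudocount of 0.5 of the median, 82 genes were lower and 91 higher, and the biogenesis median fell from 0.93 to 0.465.

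BTN2 was at 8.51 normalized reads with rapamycin and 1637 without it, the lowest log2 ratio of all kept genes at -7.17 with a counting standard error of 0.34. FES1 (YBR101C, II, 443821 to 444693), which encodes a nucleotide exchange factor of Hsp70, had a ratio of -5.27 (counting standard error 0.27). STI1 (YOR027W, XV, 381053 to 382822), a cochaperone gene of Hsp70 and Hsp90, was at 74.0 against 2320, a ratio of -4.92 (counting standard error 0.15). HSP82 was at 123 against 3714, a ratio of -4.88 with a counting standard error of 0.12. The remaining members ranged from -4.46 to -1.89, with HSC82 at -4.46 and SSA2 at -4.39 also among the 10 lowest genes. The shared Hsp70 genes SSA4 and SSA3 had ratios of -5.99 and -4.00, with the same uncertainty over reads of near-identical copies. HSP12 of the shared list had a ratio of 0.24, from 1066 to 1255 normalized reads. Outside both lists, the 10 lowest genes included ZPR1 (YGR211W, VII, 915241 to 916701), which encodes a folding factor of elongation factor 1A, at -4.99, LST8 at -4.85, and YLR217W at -4.49, a dubious open reading frame that overlaps CPR6. Together the Hsf1 list and the shared list held 32 of the 132 lower genes.

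Ribosomal protein genes had a median of 1.03 against a random range of 0.03 to 0.27, and ribosome biogenesis genes a median of 0.93 against -0.14 to 0.15. The median biogenesis gene had 6.42 normalized reads at 39 °C without rapamycin and 15.69 with it, and NOP4 and UTP4 stood on 4 reads each without it. These 2 lists held 100 of the 246 higher genes that passed the filter. The 10 highest were NOP4 at 2.02, LCP5 at 2.02, NHP2 at 2.003, the ribosome recycling gene RLI1 at 1.97, RPL37B at 1.97, UTP21 at 1.93, UTP4 at 1.904, BUD28 at 1.904, DIP2 at 1.899 and RPL26B at 1.88. BUD28 is a dubious open reading frame that overlaps RPL22A. RPL37B was at 312 with rapamycin and 77.6 without it. Respiration genes had 5 of 36 members higher, all 36 above 0 and a median of 0.75 against a random range of -0.14 to 0.28, led by COX8 at 1.47 and CYC1 at 1.26. Across 4418 genes the log2 ratio of this comparison went with gene length, shorter genes being higher, with a Spearman rho of -0.373 over genes, which are not independent replicates. With that trend removed, the medians were 0.803 for ribosomal protein genes, 0.978 for ribosome biogenesis genes and 0.534 for respiration genes.

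Proteasome genes had a median of -0.47 against a random range of -0.21 to 0.22, with 32 of 33 below 0 and none past 2-fold, led by RPN2 at -0.77 and PRE1 at -0.72. Drug resistance genes had a median of -0.36, with SNQ2 at -1.21 past 2-fold and YOR1 at -0.62, and glycolysis genes a median of -0.15, with TDH1 at -1.31 past 2-fold and PGK1 at -0.94. Both medians lay just below their random ranges, of -0.32 to 0.46 and -0.13 to 0.66. Without the length trend they were -0.24 and -0.232, and with equal totals the glycolysis median was -0.024. The other 9 lists were inside theirs, as was the Msn2/4 list. Medians were 0.01 for endoplasmic reticulum folding genes with none past 2-fold, 0.24 for ribosome-associated and TRiC chaperones with 4 of 20 higher, 0.12 for Yap1 genes with 1 higher, under the filter, and -0.09 for nitrogen catabolite genes with 1 lower. They were 0.19 for Gcn4 genes with 1 higher, -0.10 for reference genes with none, 0.08 for histone genes with none, 0.22 for the phosphate regulon with 1 higher and 0.28 for pheromone genes with none. Without the length trend the histone, Yap1, endoplasmic reticulum and Msn2/4 medians turned to -0.392, -0.042, -0.044 and -0.024. Rescaled to equal totals, the nitrogen catabolite and reference gene medians turned to 0.027 and 0.025.

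Members with the largest differences were HXK1 at -0.85 and OM45 at 0.69 in the Msn2/4 list, SIL1 at 0.77 and DER1 at 0.76 in the endoplasmic reticulum list, and SSB2 at 1.48 and YKE2 at 1.295 among the ribosome-associated chaperones. They were SRX1 at 1.46 and AHP1 at -0.81 in the Yap1 list, DUR3 at -1.16 and CAN1 at -0.86 in the nitrogen list, and LEU9 at 1.69 and ILV3 at 0.76 in the Gcn4 list. TAF10 at 0.65 and TFC1 at -0.52, HTZ1 at 0.95 and HTA2 at -0.71, PHO84 at 1.27 and VTC1 at 0.49, and FUS1 at 0.92 and BAR1 at 0.80 held these places in the reference, histone, phosphate and pheromone lists. YKE2, SRX1, FUS1 and BAR1 were under the filter. Rescaled to equal totals, 333 genes were higher and 103 lower, and the median of all kept genes shifted to 0.135.

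**Figure D2:**
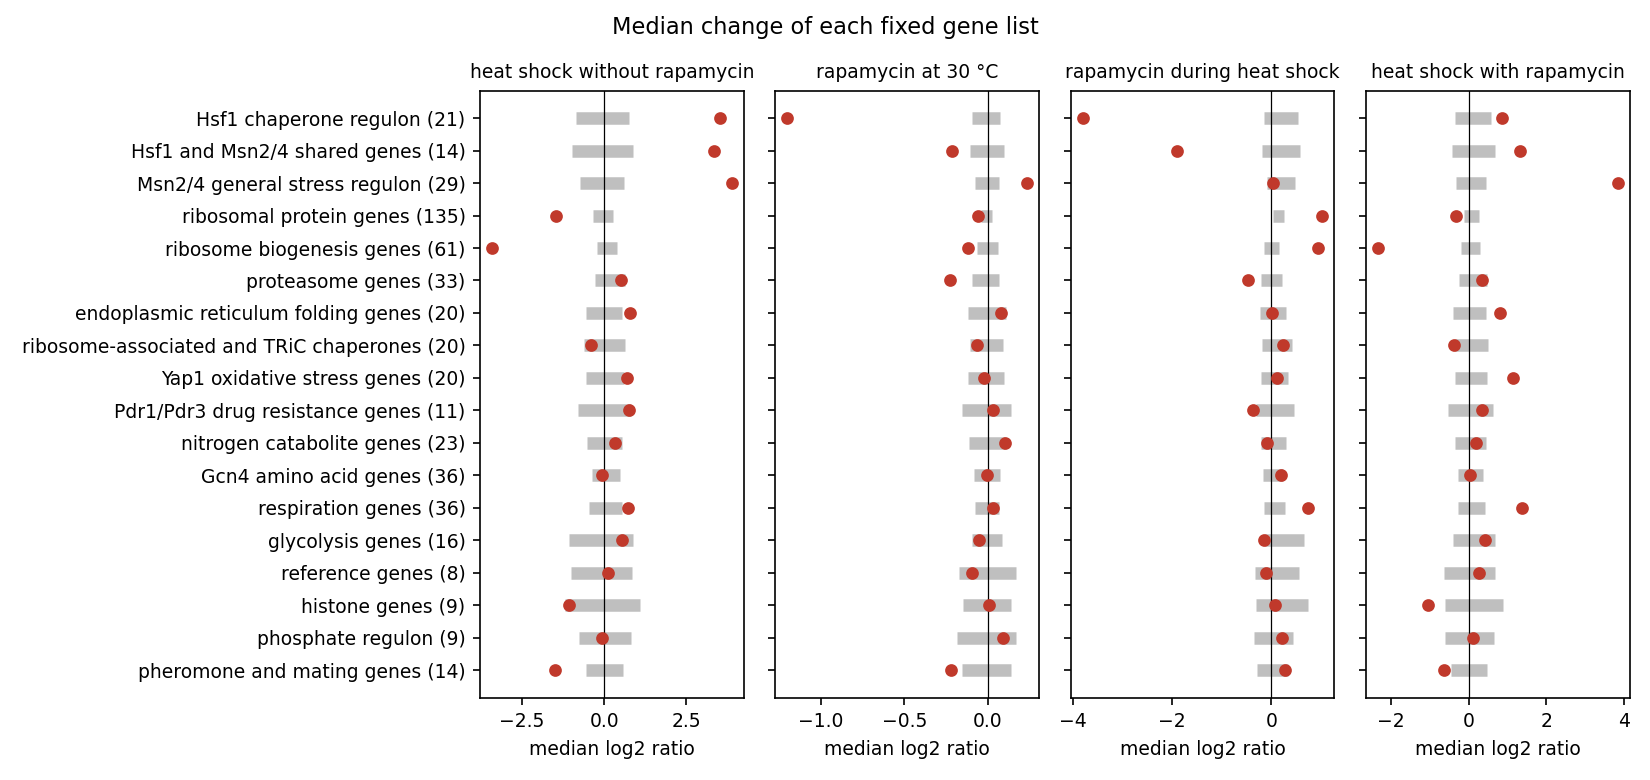
Median log2 ratio of each of the 18 gene lists (red points, with the number of measured members after each name) in the 4 comparisons, each panel with its own horizontal scale. Grey bars span the middle 95% of medians of 10000 random lists matched on mean expression. The Hsf1 regulon lies at -1.20 and -3.81 in the 2 rapamycin panels and the Msn2/4 regulon at 3.88 and 3.83 in the 2 heat shock panels.

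The fourth comparison asks what heat shock does to transcription once rapamycin has been given. With rapamycin, 566 genes were at least 2-fold higher and 588 at least 2-fold lower at 39 °C than at 30 °C. The lower count was 361 with a pseudocount of 0.5 of the median. Of the 18 lists the Msn2/4 regulon had the highest median, 3.83, next to 3.88 without rapamycin, and all 29 members were past 2-fold. Taken gene by gene, 24 of the 29 had a lower ratio with rapamycin, with a median difference of -0.33. The Hsf1 chaperone regulon had 10 of 21 members at least 2-fold higher and 1 lower, with a median of 0.85, next to 3.53 without rapamycin. All 61 measured ribosome biogenesis genes were lower again, with a median of -2.34, while 12 of 135 ribosomal protein genes were lower, with a median of -0.33.

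The highest genes were HSP12 at 6.60, FMP45 at 6.06, the phosphoglucomutase gene PGM2 at 5.87, CTT1 at 5.69, PHM7 at 5.42, TSL1 at 5.33, YER067C-A at 5.28, YNR034W-A at 5.00, DCS2 at 4.82 and HSP42 at 4.64. YER067C-A had no match in the RefSeq gene table and may share reads with RGI1 (YER067W), at 4.56. HSP42 went from 10.8 to 337 normalized reads, and HSP78 with a ratio of 3.65, HSP104 with 3.45 and HSP82 with 3.42 followed it in the Hsf1 list. HSP104 went from 68.1 to 774, with a counting standard error of 0.12 on the log2 ratio. The remaining members ranged from -1.07 for YDJ1, a J-protein gene, to 2.63 for SSA1. The shared list had 8 of 14 members higher and a median of 1.33, with HSP26 at 4.06. The 10 lowest genes were YGR160W at -4.48, NSR1 at -4.05, NOG2 at -3.84, INA1 at -3.79, the glucose transporter gene HXT1 at -3.51, the RNA helicase gene DBP2 at -3.47, NOG1 at -3.30, RSA4 at -3.27, the adenine deaminase gene AAH1 at -3.17 and ESF1 at -3.14. RPL9B at -2.33 and RPS27A at -1.76 were lowest among the ribosomal protein genes.

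Respiration genes had 29 of 36 members higher and a median of 1.36, led by MDH1 at 2.54 and SDH1 at 2.45. Yap1 genes had 10 of 20 higher and a median of 1.14, led by SRX1 at 2.28, under the filter, and PRX1 at 2.06. Endoplasmic reticulum folding genes had 7 of 20 higher and a median of 0.81, led by MPD1 at 1.93 and SIL1 at 1.76. These 3 medians were above their random ranges, of which the highest bound was 0.46. The Yap1 median was 0.687 with a pseudocount of 0.5 of the median. Histone genes with 5 of 9 lower and a median of -1.06, and pheromone genes with 5 of 14 lower and a median of -0.64, were below theirs. The pheromone median was -1.051 with the filter at the 40th percentile. HTA2 at -1.46 and HTA1 at -1.34, and MF(ALPHA)1 at -2.89 and STE3 at -2.58, were their lowest members. Ribosome-associated and TRiC chaperones had a median of -0.372, just below their random bound of -0.367, and none of 20 past 2-fold, with CCT8 at -0.96 and SSB1 at -0.89.

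The other lists were inside their ranges, with medians of 0.33 for proteasome genes, 0.35 for drug resistance genes, 0.20 for nitrogen catabolite genes, 0.02 for Gcn4 genes, 0.41 for glycolysis genes, 0.27 for reference genes and 0.10 for the phosphate regulon. Past 2-fold were none of 33, 3 higher of 11, 4 higher and 1 lower of 23, 2 higher and 2 lower of 36, 1 higher of 16, none of 8, and 2 lower of 9. Their widest members were PRE5 at 0.88 and RPT6 at 0.79, YOR1 at 2.0 and PDR15 at 1.62, PUT1 at 1.89 and UGA1 at 1.33, ILV3 at -1.54 and LEU9 at -1.26, TDH1 at 2.95 and ENO1 at 0.98, UBC6 at 0.53 and TUB2 at 0.43, and PHO5 at -1.49 and VTC1 at -1.25. Rescaled to equal totals, the Gcn4 and phosphate medians turned to -0.082 and -0.004, and with the filter at the 40th percentile the nitrogen catabolite median turned to -0.111.

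The design also allows the rapamycin difference at 39 °C to be set against that at 30 °C, which equals the heat shock difference with rapamycin minus that without it. This difference of log2 ratios was at least 1 for 317 genes and at most -1 for 172, or 124 and 80 with a pseudocount of 0.5 of the median. The Hsf1 regulon had a median of -2.10 with 20 of 21 members at or below -1, and the shared list a median of -1.61 with 10 of 14. Ribosomal protein genes and ribosome biogenesis genes had medians of 1.097 and 1.08, with 79 of 135 and 33 of 61 at or above 1. Respiration genes had a median of 0.73, above their random range of -0.19 to 0.29. The Msn2/4 list had a median of -0.33 with 1 of 29 at or below -1, below its random range of -0.15 to 0.46. The Msn2/4 median was -0.152 and the biogenesis median 0.622 with a pseudocount of 0.5 of the median.

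The 5 smallest values were -5.83 for SSA4, -5.70 for BTN2, -4.54 for ZPR1, -4.28 for SSA3 and -4.15 for FES1. The 5 largest were 2.34 for NHP2, 2.28 for LCP5, 2.25 for NOP4, 2.20 for MAK16 and 2.14 for TRZ1. The other lists had medians of -0.16 for proteasome, -0.09 for endoplasmic reticulum folding, 0.20 for ribosome-associated and TRiC, 0.11 for Yap1, -0.34 for drug resistance, -0.28 for nitrogen catabolite and 0.18 for Gcn4 genes. They were -0.11 for glycolysis, -0.11 for reference, 0.07 for histone, 0.13 for phosphate and 0.44 for pheromone genes. The nitrogen catabolite median lay just below its random range, and the pheromone median just above its own, at 0.288 with a pseudocount of 0.5 of the median. After removal of the length trend the histone value was -0.399, the reference value 0.032 and the Yap1 value -0.009, and with equal totals the endoplasmic reticulum value was 0.001.

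The 2 rapamycin comparisons shared all 17 genes that were lower at 30 °C, where independent lists would share 0.49 genes. They shared 11 lower genes with a pseudocount of 0.5 of the median. The 17 are SSA1, SSA2, HSP82, HSC82, HSP104, HSP78, BTN2, CUR1, SIS1, YDJ1, STI1, AHA1, HCH1, FES1, MBF1, LST8 and YAL004W. Neither of the 2 higher genes, PCL8 and LEU5, was at least 2-fold higher at 39 °C, where 0.11 shared genes would come from independent lists. Across genes, which are not independent replicates, Pearson's r was 0.168 and Spearman's rho -0.012. The 2 heat shock comparisons shared 452 higher genes, 61.1% of the 740 found without rapamycin, and 467 lower genes, 57.0% of the 820. Independent lists would share 91.4 and 105. Pearson's r across genes was 0.869 and Spearman's rho 0.838. No column enters both comparisons of a pair.

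Of the 740 genes that were higher with heat shock without rapamycin, 90, or 12.2%, were at least 2-fold lower with rapamycin at 39 °C. Of the 820 lower genes, 211, or 25.7%, were at least 2-fold higher with rapamycin. These pairs of comparisons share the column of 39 °C without rapamycin, so part of both overlaps comes from that column. Simulated values with counting error and no rapamycin effect gave 0.25 and 3.35 genes, and independent lists would give 21.3 and 44.0. The simulated values hold no spread between libraries.

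**Figure D3:**
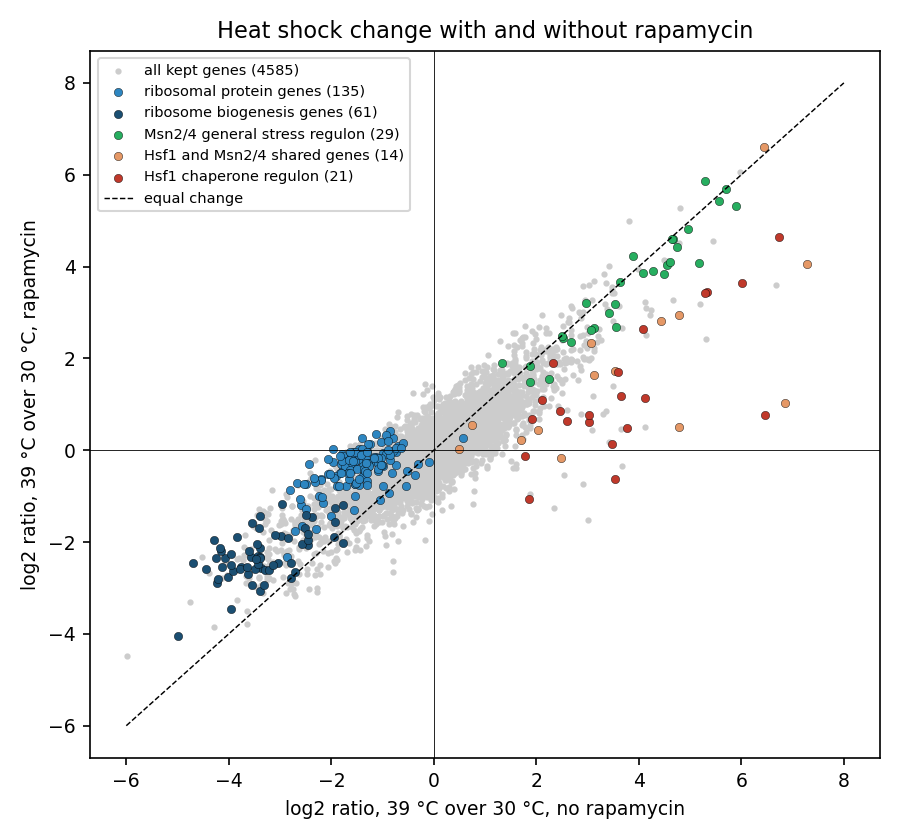
Log2 ratio of 39 °C over 30 °C without rapamycin (horizontal) and with rapamycin (vertical), 1 point per gene, with 5 gene lists coloured and a dashed line of equal change. The Msn2/4 genes lie near the line (medians 3.88 and 3.83), 24 of 29 of them below it, with a median difference per gene of -0.33. The Hsf1 regulon lies below the line (3.53 and 0.85), and ribosome biogenesis genes lie above it (-3.41 and -2.34).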

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

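The removal of the length trend and the test of a weaker heat shock below were chosen after the result was seen. The effects below differed in direction or size between conditions, and with 1 averaged value per condition none of these differences was tested.

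Ribosomal protein genes and ribosome biogenesis genes were flagged because their rapamycin medians had different signs at the 2 temperatures, each outside its random range. At 30 °C both medians were near 0, at -0.06 and -0.12, and none of the 135 and 61 members passed 2-fold. At 39 °C the medians were 1.03 and 0.93, and the differences of medians between temperatures were 1.087 and 1.054. Of the 820 genes lower with heat shock, 211 were at least 2-fold higher with rapamycin at 39 °C.

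For these lists together, 1 technical explanation meets a value that speaks against it. A length trend between the conditions as the whole cause leaves 0.803 for ribosomal protein genes once it is removed, although the trend itself was there, with a Spearman rho of -0.373. A generally weaker heat shock in the rapamycin condition stays open. The Msn2/4 list had a median of 0.035 with rapamycin at 39 °C, with 16 of 29 members above 0. Its heat shock ratios were lower with rapamycin than without it, by a median of 0.33 with 24 of 29 members below 0. That difference also holds the rapamycin ratio at 30 °C, where the median was 0.237 with 24 of 29 members above 0. With a pseudocount of 0.5 of the median, the median difference was -0.152. The 740 genes higher with heat shock had a median of -0.289 with rapamycin at 39 °C and the 820 lower genes a median of 0.638. Both go toward a weaker response, although these sets were chosen on a column that this ratio shares. They also hold all 21 Hsf1 regulon and 61 ribosome biogenesis genes, so both medians partly restate the pattern. Besides the Hsf1, shared and Msn2/4 lists, those above their random ranges with heat shock were not lower with rapamycin. Their medians went from 0.73 to 1.36 for respiration, 0.69 to 1.14 for Yap1 and 0.79 to 0.81 for endoplasmic reticulum genes. Proteasome, drug resistance, glycolysis and nitrogen catabolite medians, inside their ranges, were lower with rapamycin. Steady-state RNA carried into the rapamycin libraries cannot be told apart from a change in transcription, since the test decides nothing. The 106 other genes that were at least 4-fold lower at 39 °C with rapamycin had a median of 0.289, but they were chosen on the 39 °C column that is also the numerator of this ratio, which pulls the median down. On the biological side, loss of nuclear Hsf1 may weaken the shutdown of ribosome genes in heat shock, or rapamycin itself may act on them in heat shock. The design does not separate these. The 30 °C medians of -0.058 and -0.12, with no member past 2-fold, argue against a rise with rapamycin that needs no heat shock.

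Of the kept genes, 3 were at least 2-fold higher with heat shock without rapamycin and at least 2-fold lower with heat shock and rapamycin. YGR210C had log2 ratios of 2.34 and -1.25, a difference of -3.59. ZPR1 had ratios of 3.02 and -1.52, a difference of -4.541. YDJ1 of the Hsf1 regulon had ratios of 1.86 and -1.07, a difference of -2.932. This set was not counted under the other settings. A larger pseudocount shrinks such ratios, and the -1.07 of YDJ1 is close to the threshold. YGR210C (VII, 913503 to 914738) and ZPR1 (VII, 915241 to 916701) are adjacent and transcribed away from each other.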

How the results depend on the processing

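The removal of the length trend was chosen after the data were seen, and every other setting was fixed before. No paired analysis was possible because the table gives 1 averaged value per condition and no replicate numbers, and for the same reason no library could be left out. No value that passed its threshold changed direction under any setting run, while some medians near 0 of lists with few changed genes did. For a gene past 2-fold between 2 conditions this was fixed in advance and shows no robustness. A pseudocount, filter or threshold cannot change the sign of such a ratio. The scalings shifted the median of all kept genes by far less than 1, the furthest to -0.17. Of 350 alternative values for the counts, overlaps and 5 main lists, 278 stayed within the limits set here, and 72 moved. The limits were 1.5 times for a count, 1 SD of the random-list medians for a list, the 95% counting interval for a named gene and a 95% bootstrap over genes for a correlation. Overlaps and named genes were not run without the length trend. Of 2114 values for named genes 122 moved, and of 520 for the other lists 18 moved. Median-ratio and TMM scaling moved none of these. Their factors, from 0.993 to 1.011, leave the columns almost as deposited, so these 2 settings could move little. Equal totals, with factors from 0.938 to 1.101, did move some values. The cause of a move was not tested, except that a larger pseudocount shrinks ratios of low genes and a threshold or filter changes a count by construction. Depth limits most the condition of 39 °C with rapamycin.

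With a pseudocount of 0.01 of the median, 10 genes were higher with rapamycin at 30 °C. The Hsf1 list became -1.337 with rapamycin at 30 °C and 1.097 with heat shock and rapamycin, the shared list -0.296 with rapamycin at 30 °C and the Msn2/4 list 4.131 with heat shock and rapamycin. The ribosome biogenesis list became -3.973 with heat shock, 1.251 with rapamycin during heat shock, -2.548 with heat shock and rapamycin and 1.348 for the difference.

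With a pseudocount of 0.5 of the median, 0 genes were higher and 11 lower with rapamycin at 30 °C, 91 higher and 82 lower with rapamycin during heat shock, 361 lower with heat shock and rapamycin, and 124 higher and 80 lower for the difference, and 11 were lower in both rapamycin comparisons. The Hsf1 list became -0.945 with rapamycin at 30 °C, -3.597 with rapamycin during heat shock and -2.398 for the difference, and the shared list -0.133 with rapamycin at 30 °C. The Msn2/4 list became 3.348 with heat shock, 0.16 with rapamycin at 30 °C, 3.181 with heat shock and rapamycin and -0.152 for the difference. Ribosomal protein genes became 0.912 with rapamycin during heat shock and 0.96 for the difference. Ribosome biogenesis genes became -2.309, 0.465 and -1.784 with heat shock, rapamycin during heat shock and heat shock with rapamycin, and 0.622 for the difference.

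Without the filter 5 genes were higher with rapamycin at 30 °C, and with the filter at the 40th percentile 0 were. The correlation of the heat shock comparisons was 0.85 and 0.881 under these filters. With the latter, medians near 0 changed sign for Yap1, drug resistance and phosphate genes with rapamycin at 30 °C, to 0.035, -0.018 and -0.029, and for nitrogen catabolite genes with heat shock and rapamycin, to -0.111. With equal totals ribosomal protein genes became -1.65 with heat shock, -0.025 with rapamycin at 30 °C, 1.145 with rapamycin during heat shock, -0.435 with heat shock and rapamycin and 1.181 for the difference. Ribosome biogenesis genes became -0.087 with rapamycin at 30 °C and 1.022 with rapamycin during heat shock. With the length trend removed, ribosomal protein genes became -1.294 with heat shock, 0.803 with rapamycin during heat shock and 0.835 for the difference.

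At 1.5-fold, 1257 genes were higher and 1296 lower with heat shock, 73 and 64 with rapamycin at 30 °C, 716 and 489 with rapamycin during heat shock, 1048 and 1095 with heat shock and rapamycin, and 805 and 614 for the difference. The rapamycin comparisons then shared 6 higher and 38 lower genes, and the heat shock comparisons 848 higher and 848 lower. At 3-fold these counts were 376 and 450, 0 and 7, 32 and 61, 253 and 255, and 62 and 54. The rapamycin comparisons then shared 7 lower genes, and the heat shock comparisons 209 higher and 228 lower.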

Other observations

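All tests in this part were chosen after the results were seen. Genes named here were chosen after their values were seen.

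Genes beside Hsf1 targets were followed across the 35 genes of the Hsf1 and shared lists. Of 11 neighbours transcribed divergently from a target, 9 were at least 2-fold higher with heat shock without rapamycin and 7 at least 2-fold lower with rapamycin at 39 °C, with medians of 1.18 and -1.19. The 7 are LST8 beside SIS1 at -4.85, YAR1 beside HSP82 at -3.99, TAH11 beside SSC1 at -3.72, EFB1 beside SSA1 at -1.62, LCB5 beside HSP60 at -1.26, MTQ1 beside YDJ1 at -1.19 and BUD7 beside MBF1 at -1.01. The gaps between these genes and their targets ran from 445 to 858 bp, with a median of 742 bp. Of the 7 genes, LST8 is the only one that was also at least 2-fold lower with rapamycin at 30 °C.

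The 31 neighbours on the 3′ side of a target had a median of 0.029 and 3 genes at least 2-fold lower, of which YBL005W-B beside PDR3, at -1.05, is a Ty element gene. The 3′ neighbours do not include the divergent genes, so this median tests no explanation of the divergent genes. For the divergent genes a regulatory region shared by the pair stays open. Their median lay at percentile 0.0 of random lists matched on mean expression, which restates the pattern and does not test it. The 22 neighbours in tandem on the 5′ side had a median of -0.626 with 7 at least 2-fold lower. For these tandem genes, antisense transcription from the target promoter counted without strand stays open, and the value was seen before this was considered. Such a transcript would enter a divergent gene in that gene's own direction. There it would be counted under any strand setting, and it was not tested. Across 870 other divergent pairs the Pearson r of the rapamycin ratio at 39 °C was 0.283, against 0.119 over 874 convergent and 0.107 over 1620 tandem pairs. A test of either explanation needs reads by strand and position.

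RPO21, the gene of the largest RNA polymerase II subunit, ranked 1, 2, 13 and 5 among all genes at 30 °C without and with rapamycin and at 39 °C without and with rapamycin. Its values were 6186, 4938, 3364 and 3957, and it held 1.64% of the column total at 30 °C without rapamycin. The values are not divided by length and RPO21 is 5202 bp long, but per kb it still ranked 41, which leaves open how much length contributes. RPO21 was 113.3 times the median of 10 other RNA polymerase II subunit genes, which was 40.7 with a range of 21.0 to 185. This restates its high value and supports no explanation. Mature RPO21 mRNA bound through tagged Rpb3 while its product assembles cannot be told apart from transcription, since the table does not separate mature from nascent reads, and no biological explanation was tested.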
